A study of Arabidopsis thaliana with 6 samples.

How the data were processed

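The study profiled roots of Arabidopsis thaliana, ecotype Columbia, in wild type (WT) and in the apl mutant. Per the labels' protocols, roots were protoplasted, GFP-positive protoplasts were collected by fluorescence-activated cell sorting, and total RNA was labelled with biotin and hybridised to Affymetrix arrays by the manufacturer's protocol. The labels call the tissue phloem. The design text states 3 biological replicates per genotype, so p-values measure the spread between biological replicates. The reporter behind the GFP signal is not given in the sources used here.

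The authors deposited 1 value per probe set and array, and these values are on a log2 scale. The scale was read from the values, which lie between 2.91 and 14.10, above the largest natural or decimal logarithm of a scanner value. Array medians lay between 5.64 and 5.72, so the authors' values had already been made comparable between arrays, by a method that is not given in the sources used here. Scanner files were not used here, so background correction, probe-level effects and detection calls could not be examined. For arrays the number of arrays limits the precision. The table held 22810 probe sets, of which 64 are the manufacturer's controls and 22746 were tested. No array duplicated another.

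Gene names came from the platform annotation given with the data, which can be old, joined by gene ID to a RefSeq gene table of assembly TAIR10.1. The platform table listed 14016 of the 22746 probe sets. It gave 1 gene for 13513 of them, of which 13436 matched the RefSeq table and 77 did not, and several genes for 503. The other 8730 probe sets are unnamed here, which does not mean that they lack a gene. The named probe sets stood for 13355 genes, and 147 of those genes had more than 1 probe set. A gene with several probe sets was represented by the one with the highest mean, and no gene named in the text by the rule below had a further probe set naming it alone. Levels of different probe sets were not compared with each other. No coordinates are given because the build of the files is not named.

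The difference between genotypes was fitted per probe set with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no trend, no covariate, two-sided), as apl minus WT on the log2 values as deposited. P-values were adjusted by Benjamini-Hochberg over the 22746 probe sets, and an adjusted p below 0.05 counted as a change. A fold is 2 to the power of the log2 difference. Every adjusted p for a gene in the text comes from this limma fit unless another setting is named. The 64 control probe sets were fitted in a separate limma model with adjustment over those 64.

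Gene lists were tested with camera in limma, with its preset inter-gene correlation of 0.01, on 1 probe set per gene, for lists with at least 5 measured genes, with Benjamini-Hochberg adjustment over lists. Before the data were examined, 20 lists were written by locus code and 1, photosynthesis, by a symbol rule. Of the 325 loci in the 20 lists, 62 were named on the array. The lists for the APL pathway, for callose and plasmodesmata and for the root cap had no named probe set, and 12 further lists had under 5 and were described without a list test. That left 6 planned lists. A planned rule for ribosomal proteins needed gene descriptions, which the tables used here do not carry, so a list by locus code took its place. It belongs to a family of added lists chosen after the annotation was seen and before any genotype difference was computed, of which 36 had at least 5 genes. They were adjusted as a family of their own. A list of 21 other nuclear chloroplast genes was written after the photosynthesis result and before its own values were seen.

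The genes named in the report follow a rule fixed before the data were examined. APL itself and the APL pathway come first where measured. Then come, among probe sets naming 1 gene, past the threshold, with all 3 apl values beyond all 3 WT values and a brighter group mean above the median of all probe sets (5.75), the 15 largest rises and the 15 largest falls. Last come up to 4 members of each list with the smallest p, from which the examples of the added lists were also taken. Exceptions are marked in the text.

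The fit was tested on simulated data for this comparison, with 22746 probe sets drawn from the real means and spreads and 200 of them changed. It recovered 66% of the 100 seeded changes of 1 on the log2 scale and 89% of the 100 seeded changes of 2, with 16 false calls among 171 and 0 calls in the wrong direction. A simulated shift of -0.5 in the ribosomal protein list was called, and 0 of the 41 other lists were. Means and spreads do not carry the correlation between genes of the real arrays, estimated at 0.785 for that list. The simulation therefore does not tell how often lists are called falsely in the real arrays.

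The settings varied, chosen before the data were examined, were quantile normalization, median centring, filters at the median and at the lower quartile of the probe-set means, a trended robust variance, array weights, a floor of 16 added on the linear scale, the replicate numbers as a block, each array left out, a difference of at least 1, an adjusted p below 0.01, camera with an estimated correlation, and fry. 1 alternative was added after seeing the data, the mean of the poly-A spike controls (dap, lys, phe, thr) per array as a covariate.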

Results

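The data are 6 Affymetrix arrays of GFP-positive protoplasts sorted from Arabidopsis roots, 3 from wild type (WT replicates 2, 3 and 4) and 3 from the apl mutant (apl replicates 1, 2 and 3). APL is a MYB-type transcription factor needed for phloem identity in the root, and the series set out to find its targets by comparing the sorted cells of the 2 genotypes. Values are log2 probe-set summaries, so a difference of 1 is a 2-fold change. Correlations between arrays over 22746 probe sets were 0.985 to 0.990 within WT, 0.978 to 0.987 within apl and 0.892 to 0.938 between the genotypes. The first principal component held 79.9% of the variance and separated the genotypes. Values below are means ± SD over n = 3 arrays per genotype.

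APL itself could not be checked, because the annotation used here names no probe set for it or for the other members of its pathway list (NAC045, NAC086 and NEN1 to NEN4). The labels were therefore not tested against the mutated gene. Whether the sort took the same mix of cell types from both genotypes was not tested either. A difference given below can thus lie in expression within a cell type or in that mix. The genotypes differed at 6314 of the 22746 probe sets (27.8%) in the limma fit at an adjusted p below 0.05. Of these 2975 were higher in apl, naming 1558 genes, and 3339 were lower, naming 1808 genes. A difference of at least 1 on the log2 scale was reached by 1727 of the higher and 1474 of the lower probe sets. All 3 apl values lay beyond all 3 WT values at 42.4% of probe sets, where chance gives 10%. Without WT replicate 4 the number higher was 1983, so the count depends on the arrays by a factor of 1.5. The poly-A spike controls, bacterial transcripts added to the sample RNA before labelling, were lowest in apl replicate 2, whose mean over these controls was -1.13 from the mean of all arrays, and highest in WT replicate 2, at 0.87. Without apl replicate 2 the counts were 2518 higher and 2882 lower.

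Among probe sets naming 1 gene, with the genotypes apart and the brighter mean above the median of all, the largest rise was that of ICL (AT3G21720), the isocitrate lyase of the glyoxylate cycle, from 4.21 ± 0.21 in WT to 9.60 ± 0.78 in apl, a 42.0-fold difference (log2 difference 5.39, SE 0.38, adjusted p 0.000296). The largest rise of any probe set was 6.34, at a probe set without a gene name here. The next genes after ICL were 2 of chitinase families. ChiC (AT4G19810) rose from 4.06 ± 0.13 to 9.35 ± 0.44, 39.2-fold, and AT2G43590 from 7.04 ± 0.38 to 12.22 ± 0.60, 36.2-fold. The rest of the 15 largest rises included the class III peroxidases AT5G64120 (34.8-fold), AT5G15180 (21.8-fold) and AT2G37130 (21.5-fold), the aspartyl protease AT5G48430 (30.3-fold), and the papain-type cysteine proteases AT4G16190 (25.5-fold) and AT1G29090 (21.7-fold). The osmotin OSM34 rose from 3.63 ± 0.25 to 8.01 ± 0.20 (adjusted p 5.87e-05). The cytochrome P450 CYP71B6 rose 24.0-fold and the MATE-type transporter AT5G65380 22.3-fold. The others were the lipid-transfer-type genes AT5G01870 and AT1G62510 and the gene AT4G29200 (from 3.77 to 8.14). AT5G01870 varied most between the apl arrays, at 9.77 ± 2.24, with an adjusted p of 0.0109. Its difference was 5.17, and 3.96 without apl replicate 2 and 6.17 without apl replicate 3.

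The order and size of the rises from dim WT values depend on the setting. The bacterial trpn control probe sets lay between 3.24 and 3.84, so OSM34 and AT4G29200 are not shown to be above background in WT and their folds are not given. With a floor of 16 added on the linear scale the log2 differences were 3.27 for OSM34, 3.33 for AT4G29200, 4.36 for ChiC and 4.52 for ICL, all still past the threshold. AT2G43590, at 5.02, was then the largest of the 15. Without apl replicate 2 ICL was at 4.95 and ChiC at 5.05.

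The largest fall was that of SBT4.12 (AT5G59090), a subtilisin-type protease, from 12.78 ± 0.16 in WT to 6.81 ± 0.49 in apl, 62.7-fold (log2 difference -5.97, SE 0.25, adjusted p 6.57e-05). A further subtilase, AT1G32970, fell 21.5-fold. The peroxidase AT3G21770 fell from 12.88 ± 0.29 to 8.08 ± 0.65, 27.9-fold, so members of the class III peroxidases were among the largest changes in both directions. ATC, a relative of the flowering regulators TFL1 and FT, fell from 10.89 ± 0.63 to 6.20 ± 0.24 (25.9-fold, adjusted p 0.000259). Further falls were those of the pectin methylesterase gene ATPMEPCRD (25.3-fold) and the dirigent-like genes AT4G11210 (log2 difference -4.56) and AT4G11190 (-4.37). AT1G26450, which encodes a carbohydrate-binding X8 domain, fell 26.1-fold. The AAA-type ATPase gene AT3G28600 fell 30.2-fold (log2 difference -4.92, and -5.56 without apl replicate 3) and the hydrolase gene AT3G15650 34.9-fold. The remaining falls were AT3G59370 (41.4-fold), AT5G40980 (36.3-fold), AT1G10380 (26.9-fold), AT5G47920 (20.8-fold) and AT2G36650 (19.9-fold). Adjusted p-values of these 15 falls ran from 5.87e-05 to 0.00151.

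**Figure D1:**
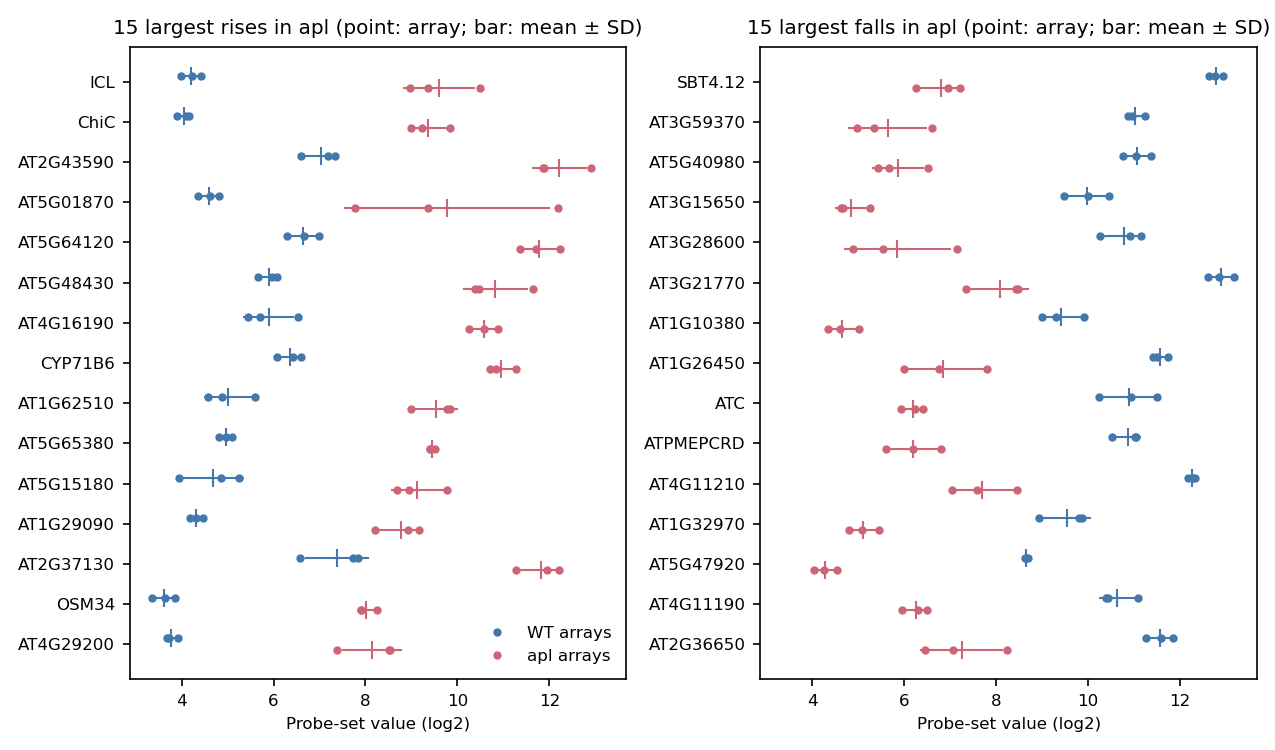
Values (log2) of the 15 largest rises and 15 largest falls among probe sets naming 1 gene, with each array as a point and the genotype mean ± SD (n = 3) as a bar. The genotypes do not overlap for any of the 30 genes; SBT4.12 shows the largest fall, 12.78 to 6.81, and AT5G01870 the widest spread within apl.

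Few phloem genes carried a name. Of 3 measured protophloem genes, OPS (OCTOPUS, a membrane protein of protophloem differentiation) fell 2.36-fold, from 6.30 ± 0.27 to 5.06 ± 0.04 (adjusted p 0.00183). CLE26 and PEAR2 did not pass, with differences of -0.40 (adjusted p 0.0530) and -0.69 (adjusted p 0.0726). CLE26 passed without WT replicate 2 (-0.51, where adjusted p over all alternatives ran from 0.0148 to 0.283), and PEAR2 was at -0.45 without WT replicate 4. In the companion cell list, MYR2 passed narrowly at -0.69 (adjusted p 0.0462), and did not pass without WT replicate 2, WT replicate 4, apl replicate 1 or apl replicate 2, nor with a floor of 16 added (-0.36). With that floor CLE26 and PEAR2 were at -0.19 and -0.36, and PEAR2 passed with a trended robust variance. The apl means of CLE26 (3.59), PEAR2 (3.69) and MYR2 (3.73) lay within the range of the trpn controls, so these genes are not shown to be above background in apl. The sucrose exporter SWEET11 was 5.41 ± 0.03 in WT and 6.90 ± 1.73 in apl, where apl replicate 1 stood at 8.72 and replicate 2 at 5.27, and did not pass (adjusted p 0.227). It passed without apl replicate 2 (2.30, adjusted p 0.0318, where adjusted p over all alternatives ran from 0.0299 to 0.517), and its difference was 0.58 without apl replicate 1. Both measured procambium genes fell. The class III HD-ZIP gene PHV fell 2.44-fold (7.28 ± 0.06 to 5.99 ± 0.19, adjusted p 0.000826) and LHW, a bHLH regulator of vascular divisions, 2.28-fold (adjusted p 0.00905).

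Of 9 measured markers of other root cell types 2 passed, both higher in apl. In the cortex list AED3 rose 18.0-fold, from 4.50 ± 0.15 to 8.67 ± 0.23 (adjusted p 5.87e-05), while CO2 differed by 0.20 (adjusted p 0.259), and by 0.11 without apl replicate 3. In the epidermis list the root hair expansin gene EXPA7 rose 3.90-fold (adjusted p 0.0281), a call lost without any 1 of the 3 apl arrays (difference 1.96, and 1.34 without WT replicate 4), and EXPA18 did not pass (0.87, adjusted p 0.464). None of the 2 endodermis genes (SGN1, -0.46, adjusted p 0.573; SGN3, -0.21, adjusted p 0.843), the 2 pericycle genes (LBD16 and LBD29, both -0.23 to -0.24) or the xylem gene IRX10 (0.68, adjusted p 0.399) passed. SGN3 lay between 8.87 and 10.56 in WT and between 8.69 and 10.41 in apl, and its difference ran from -0.68 to 0.24 with 1 array left out. LBD16 passed without WT replicate 3 (-0.74, adjusted p 0.0137, where adjusted p over all alternatives ran from 0.0137 to 0.972) and was at 0.0840 without WT replicate 2. With 1 array left out SGN1 ran from -0.88 to -0.0718, LBD29 from -0.34 to -0.0742, IRX10 from 0.30 to 1.10, and EXPA18 from 0.26 to 1.61. With the spike score as a covariate IRX10 was at 1.47 and passed (adjusted p over all alternatives from 0.0354 to 0.885).

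Few proliferation genes carried a name, 3 of 26 mitotic genes and 1 of 18 DNA replication genes. In each list 1 gene passed, lower in apl. AUR1, an Aurora kinase, fell 1.94-fold (adjusted p 0.00342) and MCM7, a replicative helicase subunit, 2.36-fold (adjusted p 0.0179). AUR2 and AUR3 did not pass, with differences of 0.95 and 0.29. AUR3 passed without apl replicate 3 (0.46, adjusted p 0.0220, where adjusted p over all alternatives ran from 0.0220 to 0.638), and was at 0.19 without apl replicate 1. AUR2 was at 0.53 without WT replicate 3, and passed with array weights. None of the 5 measured genes of developmental cell death and nucleases passed; GAMMA-VPE, a vacuolar protease, differed by 0.32 (adjusted p 0.181). Adjusted over the list alone, 0 of the 5 passed in limma as well, and 0 had an unadjusted p under 0.05. DMP4 was at -0.40, and at 0.27 without apl replicate 2, and PASPA3 was at 0.36, and passed with the spike score as a covariate (0.88). Neither of the cytokinin response genes ARR15 (-0.06) and ARR16 (-0.02) passed. ARR16 lay at 3.48 in WT and 3.46 in apl, within the range of the trpn controls. It is thus not shown to be above background in either genotype. With 1 array left out ARR15 ran from -0.14 to -0.0116 and ARR16 from -0.12 to 0.0711.

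The 9 ATG8 genes, which encode the autophagosome membrane tag, divided: 4 rose, 2 fell and 3 did not pass, over all probe sets and adjusted over the list alone. ATG8H rose 2.21-fold (adjusted p 0.00600) and ATG8B 2.20-fold, while ATG8C fell 1.39-fold. The smaller changes of ATG8A (1.34-fold) and ATG8C each lost the call without at least 1 array. The defence regulators WRKY53 (9.06 ± 0.16 to 10.77 ± 0.52, 3.27-fold, adjusted p 0.00411) and WRKY6 (2.97-fold) rose, and ZAT10 did not pass (0.18, and -0.0619 without WT replicate 3). Of 5 heat shock genes, ROF2, an FKBP-type immunophilin, fell 9.70-fold (8.38 ± 0.30 to 5.10 ± 0.05, adjusted p 0.00012), and the other 4 did not pass, over all probe sets and adjusted over the list alone. HSP15.7 was at -0.37, and passed without apl replicate 3 (-0.51, adjusted p 0.0233, where adjusted p over all alternatives ran from 0.0233 to 0.371).

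Sugar transport genes also divided, with 3 of 13 higher, 3 lower and 7 not past the threshold, over all probe sets and adjusted over the list alone. The tonoplast monosaccharide transporters went opposite ways, TMT2 falling 5.77-fold (adjusted p 0.00102) and TMT1 rising 1.79-fold (adjusted p 0.00362). SWEET2 rose 2.06-fold and SWEET1 1.65-fold. Of 8 auxin response genes 1 passed, over all probe sets and adjusted over the list alone. This was the auxin-conjugating enzyme gene GH3.3, which rose 13.6-fold, from 7.80 ± 1.24 to 11.56 ± 0.34 (adjusted p 0.00447), a difference of 3.76 that was 3.05 without WT replicate 3. GH3.1 and IAA30 did not pass (0.52 and 0.38). Without apl replicate 2 GH3.1 was at 0.0775, and without WT replicate 3 IAA30 was at -0.00309.

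Most of the photosynthesis genes that rose are encoded in the nucleus. Of 8 nuclear genes 7 rose, and of 20 plastid-encoded genes 2 rose and 1 fell. Whether the labelling reads plastid transcripts as it reads nuclear ones was not tested. Of the 28 genes of the list, 9 rose, 1 fell and 18 did not pass; adjusted over the list alone, 10 rose and 1 fell. PSBW of photosystem II rose 10.6-fold (5.87 ± 0.23 to 9.27 ± 0.29, adjusted p 0.000156), the antenna gene LHCB4.1 9.65-fold (adjusted p 0.000364), and PSAE-1 of photosystem I 5.31-fold. PSAN of photosystem I rose by 2.64 from 3.67 in WT, within the range of the trpn controls, and by 1.73 with a floor of 16 added. Photosynthesis was the 1 list of the 6 planned ones to pass camera with the preset correlation (adjusted p 0.0112), with a median difference of 0.31. The call was lost with an estimated correlation (adjusted p 0.721, where adjusted p over all alternatives ran from 0.00061 to 0.721), and without WT replicate 3 (median 0.20, adjusted p 0.0698) or apl replicate 1 (adjusted p 0.0627). Without apl replicate 3 the median was 0.58. The other 5 planned lists had camera adjusted p from 0.494 to 0.857. For the cell death list the median (-0.17) and mean (-0.03) were below 0 and camera's direction, set against all other genes, was above.

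Among the 36 added lists 5 passed camera. Of 76 cytosolic ribosomal protein genes, 16 fell, 0 rose and 60 did not pass (6 fell adjusted over the list alone), with a median of -0.64 and 74 of 76 differences below 0. The largest called examples were AT5G02450 (-1.14, adjusted p 0.00103) and AT3G16780 (-1.14, adjusted p 0.0158). The list's adjusted p was 2.85e-07 with the preset correlation, and 0.770 with an estimated correlation, which was 0.785 (adjusted p over all alternatives from 9.79e-15 to 0.770). The call was also lost under fry (adjusted p 0.132). The mean over the list was 9.59 ± 0.18 in WT and 8.97 ± 0.47 in apl, where apl replicate 3 stood at 8.44. Without that array the median was -0.37.

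The other 4 lists were smaller. Of 19 plastid-encoded genes for ribosomal proteins and the plastid polymerase, 12 fell and 7 did not pass (15 fell adjusted over the list alone), among them rpl22 (3.55-fold) and rps3 (3.17-fold). The list had a median of -1.06 and an adjusted p of 8.13e-06, and of 0.393 with an estimated correlation (1.9e-06 to 0.393 over all alternatives). How well the labelling reads plastid transcripts was not tested. Of 12 subunits of the nuclear RNA polymerases 6 fell, also adjusted over the list alone, among them NRPC2 (2.72-fold) and NRPA2 (1.95-fold). The list's adjusted p was 0.0166, and 0.393 with an estimated correlation (0.00306 to 0.393 over all alternatives). This call was also lost without apl replicate 1 and with only the probe sets above the median, where the median difference was -0.82 in place of -0.45. Of 47 UDP-glycosyltransferases, enzymes that attach sugars to small molecules, 18 rose and 6 fell (20 and 6 adjusted over the list alone), with UGT73C7 up 19.8-fold and UGT84A1 8.94-fold. The list's adjusted p was 4.71e-05, and 0.393 with an estimated correlation (2.3e-05 to 0.393 over all alternatives). The median was 0.19, and from 0.12 to 1.25 over the alternatives, with 0.29 without WT replicate 4. Of 19 CYP71B cytochromes 7 rose and 1 fell, also adjusted over the list alone, the fall being CYP71B37 (15.1-fold). The list's adjusted p was 0.0166, and 0.393 with an estimated correlation (0.00471 to 0.393 over all alternatives). The median was 0.11, and from 0.0583 to 1.22 over the alternatives, with 0.0662 without WT replicate 2 and 0.18 without WT replicate 3.

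**Figure D2:**
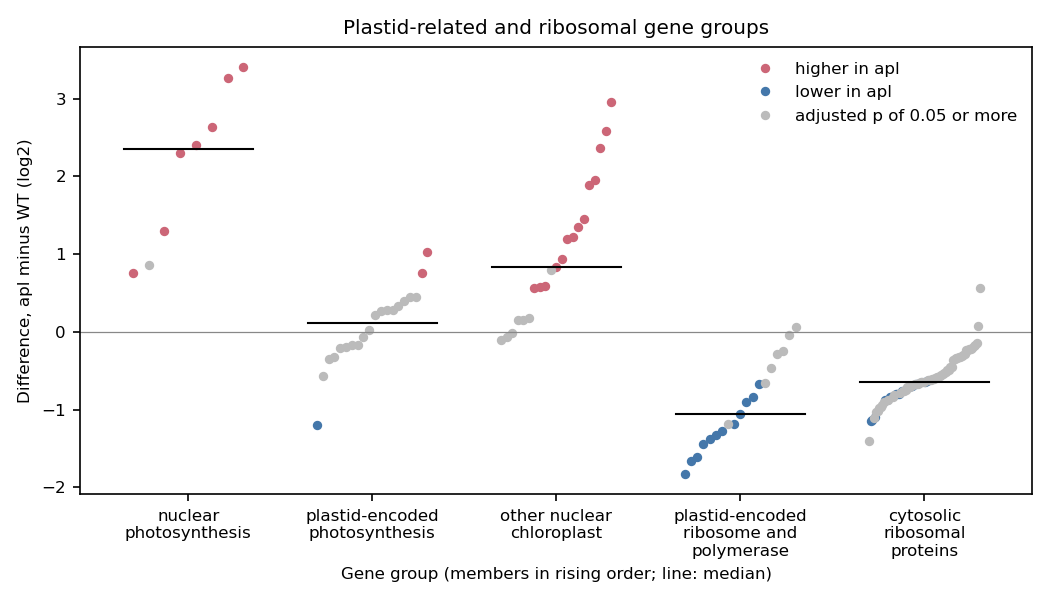
Log2 differences (apl minus WT) of single genes in 5 gene groups, members in rising order, with the group median as a line. Red and blue points passed the limma threshold; the nuclear photosynthesis genes have a median of 2.36, the plastid-encoded ones 0.12, the plastid-encoded ribosome and polymerase genes -1.06 and the cytosolic ribosomal proteins -0.64.

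The manufacturer's control probe sets, outside the counts above, gave a further measure of the samples. The actin 3' control fell from 14.07 ± 0.04 in WT to 10.05 ± 0.10 in apl (16.1-fold, limma adjusted p 3.56e-06), the middle one 3.83-fold and the 5' one 3.29-fold. In a second set of actin controls the 3' one fell 7.37-fold (adjusted p 8.67e-05) and the middle one 3.34-fold, and the 5' one did not pass (-0.55, adjusted p 0.193). The 3' controls of GAPDH (0.27, adjusted p 0.645) and ubiquitin (0.04, adjusted p 0.946) did not pass. The 25S rRNA control fell 1.65-fold (adjusted p 0.00668). The hybridisation control cre differed by 0.02 at its 3' probe set (adjusted p 0.978).

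**Figure D3:**
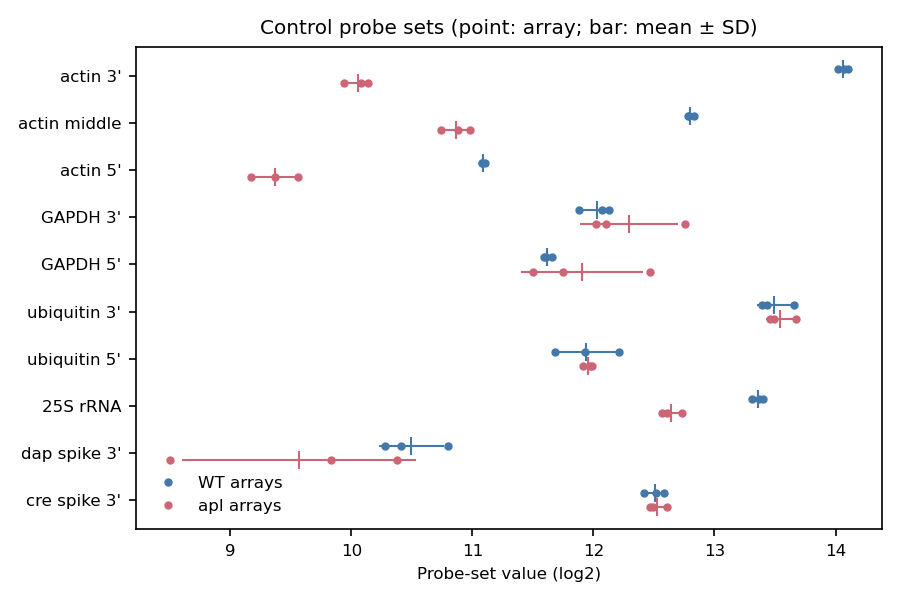
Values (log2) of 10 control probe sets, with each array as a point and the genotype mean ± SD (n = 3) as a bar. The actin 3' control lies at 14.07 in WT and 10.05 in apl, and the GAPDH and ubiquitin controls overlap between the genotypes.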

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

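The fit with the spike score and the alternative fits of the added lists were chosen after the data were seen. The other alternatives were planned. The numbers of higher and lower probe sets stayed within 1.5 times the values reported with quantile normalization, median centring, both filters, the trended variance, array weights and the added floor, with 2272 to 3623 higher and 2679 to 4177 lower. Median centring moved the share of higher calls from 47.1% to 43.7%, and no scaling moved the median of all probe sets by 0.1. With a difference of at least 1 the counts were 1727 and 1474, at an adjusted p below 0.01 they were 1625 and 1743, and with the spike score as a covariate 1923 and 1945. Leaving out 1 array gave 1983 to 2913 higher and 2257 to 3172 lower, the lowest in both without WT replicate 4. Between 66.6% and 85.6% of the reported calls were called again with 1 array left out, all in the same direction.

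With the replicate block, in which only numbers 2 and 3 occur in both genotypes, 684 were higher and 531 lower, since arrays with an unshared number then carry no information on the genotype. The numbers are not stated to pair arrays. Deviations from the genotype means correlated at -0.00665 for the arrays numbered 2 and 0.097 for those numbered 3. Of the 6 ways to match the arrays, the mean correlation was highest (0.246) for WT replicate 2 with apl replicate 1 (0.317), WT replicate 3 with apl replicate 2 (0.228) and WT replicate 4 with apl replicate 3 (0.192), a hint from the data and not the design, which was not fitted. Calls of genes whose arrays vary within each genotype, such as SGN1, SGN3 and IRX10, rest on the unpaired fit. The planned list count was 0 with the replicate block and with an estimated correlation, and 0 to 1 with 1 array left out; in the others it was 1, under fry that of heat shock (adjusted p 0.0396) in place of photosynthesis. The added list count was 0 with an estimated correlation, 15 under fry, which does not compare a list with other genes, and 4 to 5 with 1 array left out. The 15 do not include the cytosolic ribosomal protein list (fry adjusted p 0.132).

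Of 54 named genes past the threshold, 35 stayed past it in each of the up to 15 settings run for them, 0 changed sign, 18 lost the call with the replicate block, 4 when an array was left out and 5 with the spike score. Of 24 named genes not past it, 10 changed sign and 9 passed somewhere. The differences after a change of sign were as follows, none past the threshold. With array weights they were 0.30 for SGN3, -0.0353 for HSA32 and 0.12 for the cell death list. With the spike score they were 0.62 for SGN3, 0.27 for SGN1, 0.0898 for DMP4, 0.0858 for ARR16 and 0.30 for the cell death list. With the replicate block they were -0.21 for EXPA18 and -0.00485 for HSP22.0. Without WT replicate 2 they were 0.0840 for LBD16, 0.16 for SGN3, 0.0214 for ARR16, 0.0130 for the cell death list and 0.13 for heat shock. Without WT replicate 3 they were -0.0619 for ZAT10, -0.00309 for IAA30 and -0.00204 for the auxin list, and without WT replicate 4 -0.00893 for HSP22.0. Without apl replicate 2 they were 0.24 for SGN3, 0.27 for DMP4, 0.0711 for ARR16 and 0.27 for the cell death list. With 1 array left out the other ends were -0.33 for the cell death list, -0.51 for heat shock, -0.74 for LBD16, -0.68 for SGN3, -0.78 for DMP4, 0.35 for ZAT10, 0.34 for HSP22.0, 0.64 for IAA30 and -0.12 for ARR16. The cause was not tested, except that left-out arrays and stricter thresholds leave fewer arrays or calls by construction. The other settings for APL itself were not run, since no probe set is named for it. Detection over background was not given, so dim probe sets could not be told from undetected ones.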

Other observations

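Tests of the splits of the arrays, of the APL neighbourhood, of the spike controls, of apl replicate 2, of matched random lists and of the chloroplast gene list were set down before their results were seen; those of the actin controls and of apl replicate 3 were chosen after.

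Several gene families whose counts are not given above had members that rose and members that fell. Of 54 class III peroxidases 12 rose and 8 fell, among them AT5G64110 (3.71) and AT5G06730 (-3.68). Of 15 tetraspanins, membrane-organising proteins, 3 rose and 5 fell, with TET5 at -3.78 and TET3 at 1.57. Of 15 IQ-domain proteins 4 rose and 7 fell, with IQD24 at -2.27. Of 7 tubulin genes 2 rose, TUB1 by 2.77 and TUB5 by 1.71, and 4 fell, among them TUA1 and TUB7 (-1.24 and -1.26). None of the 4 measured core histone genes passed in limma, 1 had an unadjusted p under 0.05, and HTB2 had the smallest adjusted p, 0.0541. CLE41, which encodes the phloem-derived TDIF peptide that acts on the cambium, fell 13.6-fold, from 7.91 ± 0.38 to 4.14 ± 0.22 (limma adjusted p 0.000166), and CLE44, which encodes the same peptide, differed by 0.51 and did not pass (adjusted p 0.0580). Both were chosen after their values were seen. Other added lists with camera adjusted p above the threshold ran from 0.0773 to 0.999.

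The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 2975 probe sets in one direction and 3339 in the other. The highest of the other splits gave 0 in limma at the adjusted threshold and 1240 at an unadjusted p under 0.05. Each other split has arrays of both genotypes in each of its groups, so the genotype difference adds to the spread within groups. Low probe-set counts are thus built into these splits, and the 0 cannot tell whether the real count arose by chance. For lists the picture differed. The real split had 1 planned list past the threshold and the highest other split 4, and 5 of the 10 splits had at least 1. The real split had 5 added lists and the highest other split 7, and 2 of the 10 had at least 5. Some splits that mix the genotypes thus called more lists than the real one. Members of a list varying together between arrays could also raise the list counts, which was not tested. The estimated correlation was 0.785 for the cytosolic ribosomal proteins and 0.0204 for the UDP-glycosyltransferases.

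The fall of the actin controls was weighed against RNA quality. Degradation would widen the gap between the 3' and 5' probe sets of other transcripts, and the gap of the GAPDH and ubiquitin controls changed by 0.00125 (SE 0.0932), while that of actin changed by -2.29. The mean of the GAPDH and ubiquitin 3' controls changed by 0.155 (SE 0.126), so the fall was not shared by these transcripts. As the values had already been made comparable between arrays, this cannot tell whether less RNA was labelled. The 25S rRNA control differed by -0.72 and passed (limma adjusted p 0.00668), and the poly-A spike probe sets differed by -1.29 to -0.26 with none past the limma threshold. None of them fell as far as the actin 3' control (-4.01). The spikes are added to the sample RNA, so lower spike values do not show that less sample RNA was labelled. A hypothesis that remains is lower actin expression in the apl cells, whether within a cell type or through the mix of sorted cells. It was not tested. ACT11 fell 4.26-fold (limma adjusted p 0.000219), but was chosen after its value was seen and is no test of it.

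The lower values of the cytosolic ribosomal protein genes were weighed in the same way. Without apl replicate 2 the median was -0.80, and without apl replicate 3 it was -0.37, so neither array alone carries it, although apl replicate 3 adds to it. Of 10000 random lists matched on mean value 0% had a median as low as -0.64, the lowest being -0.38, which argues against a property of bright probe sets. With the poly-A spike score as a covariate the median was -0.65, and between -1.01 and -0.37 without each array in turn. The 76 genes move together between arrays (estimated correlation 0.785), so they may act as little more than 1 measurement on 6 arrays, and the genotype as cause stays open.

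The nuclear photosynthesis genes rose apart from the plastid-encoded ones. The median was 2.36 over 8 nuclear genes, of which 7 rose, and 0.12 over 20 plastid-encoded genes, of which 2 rose and 1 fell (difference of medians 2.24, p 0.00011, permutation of the 28 genes, which are not independent). This permutation was not among the tests set down beforehand. The labelling may not read plastid transcripts as it reads nuclear ones, which was not tested. Of the plastid-encoded genes psbT (3.42 in WT, 3.36 in apl) lay within the range of the trpn controls, and psbM (9.63 and 9.31) did not. With the spike score as a covariate the nuclear median was 2.71, and between 2.52 and 2.84 without each array in turn. The rise thus did not depend on that score. As the spikes do not show how much sample RNA was labelled, this cannot decide on the amount of labelled RNA. Green tissue in the apl sort would bring other abundant chloroplast transcripts. Over the list of 21 other nuclear chloroplast genes the median was 0.84 (bootstrap interval 0.57 to 1.35), with 14 higher and 0 lower. The list was not chosen by abundance, and some members were dim in both genotypes, such as NdhL (3.68 in WT, 3.67 in apl). RCA, among the most abundant leaf transcripts, rose to 7.78 ± 0.50 from 4.82 ± 0.08, and PORB rose by 2.36. The median of the 21 genes lies between the bounds set for and against, a result that depends on the members listed. Green cells and greening of root plastids cannot be told apart by it, since both raise these genes. The sort was on GFP.

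A chromosome segment carried along with the mutated locus could raise the share of changed genes near APL. Among the 50 named genes on each side of APL in gene order, 28% had changed, against 25% of the 3411 named genes on chromosome 1. This share is at percentile 66.9 of 3312 windows of the same size, whose shares ran from 5% to 40%, so no excess was seen.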
